A study of Mus musculus with 27 samples.

How the data were processed

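Bulk RNA sequencing was measured in 27 mouse samples of 9 groups with 3 libraries each. Mouse embryonic fibroblasts, which are primary cells grown out of embryos, were sampled in 2 numbered experiments. Experiment 1 held libraries labelled WT, KO and KO-NTD, and experiment 2 held libraries labelled WT, WT-NTD, Het and Het-NTD. Whole lungs of animals aged 10 days were labelled WT or Het. The labels do not explain NTD, and they do not say which part of Foxm1 was altered. Fibroblasts were of early passage, dividing asynchronously and taken at about 90% confluence, per the labels. Libraries were made from about 200 ng of RNA with a TruSeq RNA kit that does not mark strand, per the labels' protocols.

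The authors deposited 1 table of raw read counts per gene symbol, with 24062 symbols and a column for each library. Reads were aligned to the mouse genome build mm10 and the tools named are TopHat2 2.0.14, Bowtie2 2.2.6, featureCounts 1.4.6 and Subread, per the submitters' processing notes. The gene annotation and the strand setting used for counting were not given in the sources used here. Of the symbols, 22550 matched a RefSeq symbol, 23922 a symbol or synonym, and 23902 had an Entrez number. Coordinates are from GENCODE M21 on GRCm38, which is the same assembly as mm10. Total counts were 29730693 to 69517834 per library with a median of 42708114, and 15963 to 18168 genes had at least 1 count. Among genes with 1 to 30 counts, 61.5 to 67.3% of the counts were even. The cause of that excess was not tested, and counting intervals treat each count as independent, so they cover counting error only and may be too narrow. In every group the closest replicate pair differed by more than sampling noise (smallest chi-square per degree of freedom 5.88), so each library was counted as 1 sample.

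Each experiment and the lungs were fitted apart with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr by group, libraries were scaled by TMM, and contrasts were tested with the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The experiment 1 fit held 9 libraries, 14551 genes and 6 residual degrees of freedom (common biological coefficient of variation 0.204). Experiment 2 held 12 libraries, 14314 genes and 8 degrees of freedom (0.114), and the lungs held 6 libraries, 15933 genes and 4 degrees of freedom (0.255). The difference of the Het effect between tissues was tested in a joint fit of 12 libraries and 16364 genes (8 degrees of freedom, 0.21). CPM are counts normalised to the library size scaled by TMM within a fit, so CPM of the joint fit differ from those of the separate fits. The labels number the libraries but do not say whether each came from its own embryo, animal or culture, so p-values measure only the spread between these libraries. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so no exact test of single values was used.

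Lists of genes were fixed in advance for G2/M genes driven by FoxM1, G1/S genes driven by E2F, the spindle checkpoint and kinetochore, p53 targets, SRF and MRTF targets, YAP and TEAD targets, extracellular matrix, interferon-stimulated genes, senescence and secreted factors, TGF-beta targets, endoplasmic reticulum stress, cholesterol synthesis, glycolysis and hypoxia, Hox genes, imprinted genes, mitochondrially encoded genes, ribosomal proteins, immediate early genes, and Xist with Y-linked genes. Markers were fixed for alveolar type 2 and type 1 cells, ciliated and club cells, blood and lymphatic endothelium, macrophages, T cells, thymocytes, B cells, neutrophils, erythroid cells, smooth, cardiac and skeletal muscle, lung mesenchyme, mesothelium, epithelial keratins, neural and glial cells, chondrocytes, adipocytes and liver. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison. Camera was repeated with the correlation estimated from the residuals, and fry was a second test that does not compare a list with other genes. Reactome pathways of 15 to 300 tested members, from fgsea 1.28.0, were tested in the same way. A macrophage score is the mean log2 CPM of the 11 tested macrophage genes.

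Genes were named by a rule: Foxm1 first; then, among genes past the threshold with an average log2 CPM of at least 1 whose CPM did not overlap between groups and whose symbol is not a predicted model or clone name, the 10 highest and 10 lowest log2 fold changes in a main comparison and the 5 highest and 5 lowest in a secondary one; where fewer than 3 genes passed, the 3 lowest p-values; and up to 4 members of each list by p-value. The non-overlap condition was dropped for interactions. Main comparisons were KO against WT, KO-NTD against KO, Het against WT and Het-NTD against Het in fibroblasts, and Het against WT in lung. Ect2, Rhoa and the gene for mDia1 were named because the series title names them, and genes called in both KO and Het comparisons were named after their values were seen. Results of 1 further list, 1 pathway and 1 gene are not reported here. Groups, tests, lists, the naming rule and the first set of alternatives were set before the data were examined.

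Alternatives were DESeq2 1.42.0, edgeR with RLE size factors, no filter on low counts, the replicate number as a block, fits of the compared groups alone, and leaving out each library. Sex read from Ddx3y and the macrophage score as covariates, and the lungs without WT 1 and Het 3, were added after seeing the data. Comparisons that share libraries were set beside 20 simulated draws of unchanged groups. The test steps were tested on simulated data, with 50 genes changed at each fold size. For KO against WT (14429 genes), 6% were recovered at 1.25-fold, 54% at 1.5-fold, 82% at 2-fold and 92% at 4-fold, and 8 unchanged genes were called. For Het against WT in fibroblasts (14186 genes) the shares were 34, 52, 86 and 96% with 12 unchanged genes called. For the lung (15768 genes) they were 2, 2, 40 and 92% with 5. For the interaction of NTD with genotype (14170 genes) they were 6, 50, 62 and 96% with 8, and for the tissue difference (16195 genes) 0, 6, 20 and 72% with 4.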

Results

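The series compared fibroblasts and lungs of mice with altered Foxm1, a forkhead transcription factor that drives genes of G2 and mitosis. Bulk RNA sequencing counts were available for 27 libraries, 3 in each of 9 groups. In experiment 1, fibroblasts labelled WT, KO and KO-NTD had 47380829 to 69517834 counts per library. In experiment 2, fibroblasts labelled WT, WT-NTD, Het and Het-NTD had 30247046 to 46625753. Whole lungs of animals aged 10 days, labelled WT or Het, had 29730693 to 50326730. The labels do not explain NTD.

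Foxm1 was not lower in the libraries labelled KO than in wild type. Its level, in library-size-normalised counts (CPM), was 146 ± 6.64 (SD, n = 3) in KO against 136 ± 3.34 CPM in WT, a ratio of 1.07 (95% interval 0.986 to 1.17, edgeR adjusted p = 0.565). In experiment 2 it was 129 ± 2.63 CPM in the libraries labelled Het and 147 ± 1.99 CPM in WT. The 3 Het values lay below the 3 WT values, but the ratio of 0.881 (0.768 to 1.01) did not pass the test (edgeR adjusted p = 0.249). That test and interval use a spread shared by all 12 libraries of experiment 2. Foxm1 had an SD of 56.9 CPM in WT-NTD and 34.4 CPM in Het-NTD, so the result does not show that Foxm1 was unchanged in Het. The log2 change was -0.18, and -0.01 with the macrophage score as a covariate (edgeR adjusted p = 0.983), a setting added after seeing the data. The slope on that score was fitted over all 12 libraries, NTD ones included, and groups held 83.6% of the score's variance. The adjusted value therefore cannot show whether macrophages account for the Foxm1 difference. In lung, Foxm1 was 18.4 ± 1.55 CPM in Het and 19.2 ± 1.08 CPM in WT (ratio 0.961, 0.811 to 1.14, edgeR adjusted p = 1). The Foxm1 count rose in every NTD group. Reads that belong to NTD, if any, could be counted on the same gene, so a rise of Foxm1's own transcript cannot be told apart. The ratio was 2.47 (2.27 to 2.70) in KO-NTD against KO, 2.68 (2.33 to 3.08) in Het-NTD against Het and 2.36 (2.05 to 2.71) in WT-NTD against WT, with edgeR adjusted p of 1.8e-04, 3.4e-04 and 0.00137. The gene lies on chromosome 6 from 128362967 to 128376146 (GRCm38, plus strand). Its exons overlap no exon of another gene in the table. GENCODE M21 lists 8 transcripts with up to 8 exons, and a count over the whole gene does not show which exons were read. The unchanged count therefore does not bear out the label KO, nor can it contradict that label. The groups are written as labelled where directions are drawn from them.

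**Figure D1:**
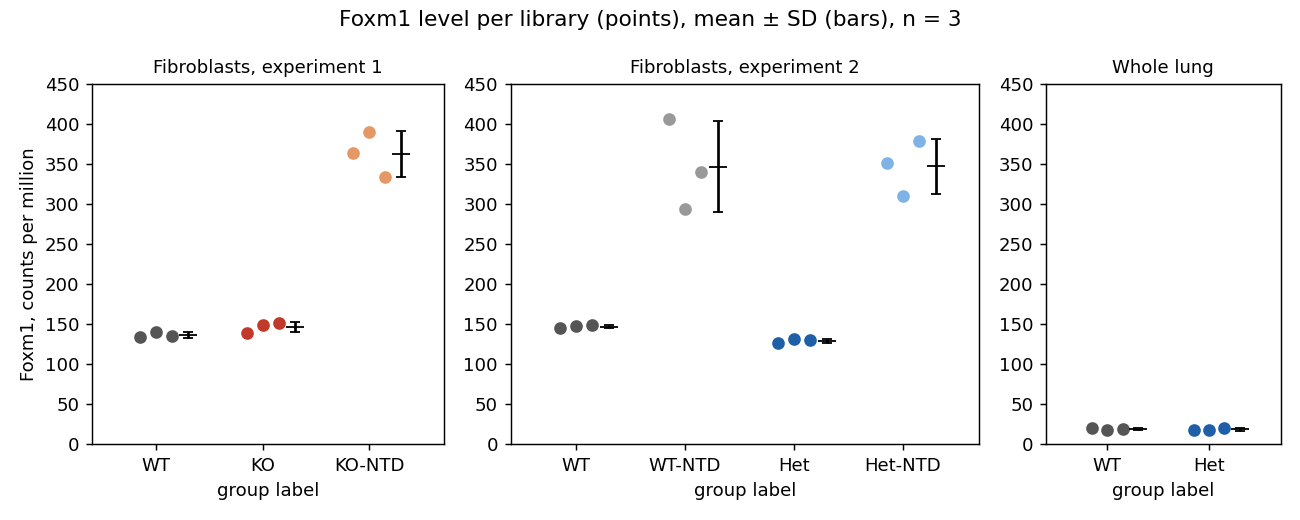
Foxm1 level in CPM for each library (points), with the mean ± SD of 3 libraries beside them, in fibroblasts of experiments 1 and 2 and in whole lung. KO (146 CPM) lies beside WT (136 CPM), the NTD groups lie at 346 to 362 CPM and the lungs at 18.4 and 19.2 CPM.

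The series title also names Ect2, the exchange factor that activates RhoA at cytokinesis, together with RhoA and the formin mDia1. Ect2 fell in the libraries labelled Het of experiment 2, from 80.0 ± 5.15 to 58.6 ± 2.95 CPM (SD, n = 3), a log2 change of -0.45 ± 0.08 (SE, edgeR adjusted p = 0.00274). It was 96.8 ± 10.4 CPM in KO and 103 ± 7.30 CPM in WT of experiment 1 (log2 change -0.09, edgeR adjusted p = 0.796), and 12.6 ± 3.24 against 15.4 ± 1.72 CPM in lung (log2 change -0.29, edgeR adjusted p = 1). Rhoa gave log2 changes of -0.11, -0.01 and -0.06 and Diap1, which encodes mDia1, 0.16, 0.07 and 0.02 in the same 3 comparisons. None of these passed in edgeR (adjusted p from 0.287 to 1). DESeq2 called Rhoa lower in KO (519 ± 4.71 against 560 ± 13.9 CPM, DESeq2 adjusted p = 0.0321) and none of the others.

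KO against WT in fibroblasts asked what loss of Foxm1 does to expression. Genes of mitosis were among those that fell in the libraries labelled KO, whose Foxm1 was not lower. Nek2, a centrosomal kinase, fell from 51.2 ± 3.04 to 19.3 ± 1.77 CPM (SD, n = 3), a log2 change of -1.41 ± 0.08 (SE, edgeR adjusted p = 4.4e-04). Cenpf, a kinetochore protein, fell from 112 ± 16.6 to 41.9 ± 3.53 CPM (edgeR adjusted p = 0.00141), Cenpa, the centromeric histone, from 64.5 to 32.4 CPM (4.4e-04), and Ccnb1, the mitotic cyclin B, from 150 to 90.3 CPM (8.7e-04). Of the 40 G2/M genes driven by FoxM1, 14 fell and none rose, and 16 fell and none rose when adjusted over the list alone. Ccnb2, Ccna2, Ccnf, Cdc25b, Kif20a, Kif2c, Kif23, Cdc20, Aspm and Dlgap5 were among the 14. The other members lay near 0, among them the kinases Plk1 (log2 change -0.06, edgeR adjusted p = 0.656) and Aurkb (-0.02) and the topoisomerase Top2a (0.13), so the list's median was -0.07 and its mean -0.27. Camera called the list lower (adjusted p = 4.7e-10), with adjusted p = 0.889 with an estimated correlation, and fry gave adjusted p = 0.0126. None of the 35 G1/S genes passed (median -0.03, camera adjusted p = 0.375). Of 27 spindle and kinetochore genes, 1 fell, the abscission protein Cep55 (log2 change -0.84, edgeR adjusted p = 0.00359). That list had a median of 0.03 and a mean of -0.03 (camera adjusted p = 0.663). The 14 fell to 8 without WT 2 or with the KO and WT libraries alone in the fit, and to 9 without WT 3 or without KO 2, and the G1/S list was called without WT 3 (camera adjusted p = 0.0454).

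In all, 18 genes rose and 47 fell of 14551 tested in KO against WT (edgeR). Ifi204, an interferon-inducible gene of a multigene family, rose from 5.91 ± 0.32 to 15.7 ± 2.73 CPM (SD, n = 3; log2 change 1.41 ± 0.14 SE, edgeR adjusted p = 0.00406). Mlkl, the effector of necroptosis, rose from 6.28 ± 0.19 to 13.5 ± 1.36 CPM (log2 change 1.10, edgeR adjusted p = 0.0218). Emb, a chaperone of monocarboxylate transporters, rose by 1.02 on the log2 scale, the cullin Cul9 by 0.998, the intraflagellar transport gene Ift27 by 0.81, the zinc transporter Slc39a8 by 0.69, the protease inhibitor Serpine2 by 0.68 and the GTPase Rab32 by 0.66. The detoxifying enzymes Ugt1a6a (log2 change 2.86) and Ugt1a7c (1.88) also passed, but both share exons with 7 other genes of their locus, so which of them rose is uncertain. Mgp, matrix Gla protein, fell from 160 ± 17 to 39.7 ± 5.09 CPM (log2 change -2.01, edgeR adjusted p = 0.0127), and Sfn, stratifin, from 26.2 ± 4.89 to 6.02 ± 2.57 CPM (log2 change -2.12, edgeR adjusted p = 0.0308). The chloride channel Ano1 fell by 1.37 on the log2 scale, the cytoskeletal linker Gas2l3 by 1.31, the spindle protein Knstrn by 1.16, the phosphatase Cdc25b by 1.15, the spindle pole gene Aspm by 1.11 and the centriolar gene Cep89 by 1.09. Cdc25b shares exon sequence with Spef1 on the other strand, and the kit does not mark strand. DESeq2 called 479 genes, 237 higher and 242 lower. Left-out libraries moved the edgeR count of 65 to 142 without KO 1, 24 without KO 2, 31 without WT 1, 36 without WT 2 and 41 without KO 3; of the 20 named genes, Ifi204, Cenpf, Nek2, Knstrn and Cep89 passed without any 1 library.

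Other groups of genes in KO against WT had few or no members past the test. All 30 interferon-stimulated genes were above 0 with a median log2 change of 1.253, but none passed; Irf7 was 3.96 ± 2.79 CPM in KO and 1.08 ± 0.09 CPM in WT (SD, n = 3, edgeR adjusted p = 0.279). Camera gave that list adjusted p = 1.1e-06, with adjusted p = 0.889 with an estimated correlation. All 23 cholesterol synthesis genes were below 0 (median -0.16) and 21 of 25 endoplasmic reticulum stress genes were (median -0.16; 5 lower adjusted over the list alone, 0 over all genes), while 24 of 27 glycolysis and hypoxia genes were above 0 (median 0.13). Their camera adjusted p were 9.5e-04, 5.6e-05 and 0.0357, each with adjusted p = 0.889 with an estimated correlation. The glycolysis list turned its direction without KO 1 (camera adjusted p = 0.432) and was not called without WT 2 (0.0759) or WT 3 (0.0876), nor was the cholesterol list without WT 3 (0.216). Among 27 p53 targets Ckap2, a microtubule gene, fell (log2 change -0.65, edgeR adjusted p = 0.00764) while the median was 0.15 (camera adjusted p = 0.0159). Of 26 SRF targets Fhl1 fell by 0.63 and the smooth muscle actin Actg2 by 0.95 on the log2 scale (median -0.09, camera adjusted p = 0.012), and Actg2 was also the 1 of 8 smooth muscle genes that fell (median -0.11, camera adjusted p = 0.0372). These 3 lists each had adjusted p = 0.889 with an estimated correlation. The call of p53 targets ended without KO 1 (camera adjusted p = 0.378), that of SRF targets without WT 2 (0.2), KO 2 (0.243) or KO 3 (0.128), and that of smooth muscle genes without WT 1 (0.0617), WT 2 (0.144), KO 2 (0.244) or KO 3 (0.184). None of the 22 YAP targets passed (camera adjusted p = 0.551; 3 lower adjusted over the list alone), nor any of 30 matrix genes (0.29), 24 senescence genes (0.6), 19 TGF-beta targets (0.547), 36 Hox genes (0.566), 18 imprinted genes (0.114), 33 ribosomal protein genes (0.283) or 15 immediate early genes (0.892). Macrophage genes differed within the KO group: their score was -0.84, 4.15 and 3.65 in KO 1, 2 and 3, and 2.50, 1.74 and 2.02 in WT 1, 2 and 3. Of 687 Reactome pathways none passed.

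Het against WT in experiment 2 asked what loss of 1 copy of Foxm1 does in fibroblasts. Of 14314 genes tested, 1130 rose and 1232 fell (16.5%, edgeR), and 185 rose and 502 fell by at least 2-fold. The mitochondrial carrier Ucp2 (chromosome 7, 100493337 to 100502020, GRCm38) rose from 16.7 ± 1.60 to 167 ± 7.73 CPM (SD, n = 3), a log2 change of 3.33 ± 0.07 (SE, edgeR adjusted p = 3.6e-11). Its exons overlap those of Dnajb13 on the other strand. Brinp3, a neural gene, rose by 3.69 on the log2 scale, the retinol carrier Rbp4 by 2.97, the receptor gene Tnfrsf26 by 2.45, Hhipl1 by 2.44, the protocadherin Pcdh1 by 2.40, the peptide hormone Cck by 2.29, the membrane glycoprotein Cd200 by 2.23, Naalad2 by 2.10 and the ion channel Asic3 by 2.09. Trim12a, of a multigene family with near-identical copies, fell to 8 counts over the 3 Het libraries from 561 in WT, a WT to Het ratio of 73.9 (95% counting interval 37.2 to 172). In experiment 1 Trim12a ranged from 0 to 1.76 CPM within WT and from 0.0356 to 2.14 CPM within KO-NTD. The synaptic adhesion gene Lrrtm3 fell to 9 from 642 counts (ratio 75.2, 39.4 to 165). The patterning factor Msx1 fell by 4.09 on the log2 scale, Olfml1 by 3.98, the opioid precursor Penk by 3.90, the fatty acid receptor Cd36 by 3.77, the growth factor Gdf10 by 3.63, the scavenger receptor Stab1 and the macrophage marker Emr1 by 3.09 each, and the cytokine receptor Il31ra by 2.98 (edgeR adjusted p from 5.6e-06 for Trim12a to 0.0398 for Penk). DESeq2 called 1314 genes higher and 1582 lower. Without Het 3, Het 2 or WT 2, edgeR called 1304, 1534 and 1565 genes; Cd200 did not pass without WT 3 (edgeR adjusted p = 0.0744), nor Gdf10 or Penk without Het 3 (0.0627 and 0.129).

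Cell cycle genes fell as groups in the libraries labelled Het. Of the 40 G2/M genes 29 fell and 1 rose, or 35 and 1 adjusted over the list alone. The median log2 change was -0.31. Nek2 fell from 52.4 ± 1.79 to 34.6 ± 2.47 CPM (SD, n = 3; log2 change -0.60 ± 0.06 SE, edgeR adjusted p = 1.5e-04), the mitotic kinase Plk1 from 143 to 99.2 CPM and the kinesin Kif20a from 169 to 128 CPM. Pttg1, which encodes securin, was the 1 that rose (log2 change 1.38, edgeR adjusted p = 1.5e-04). Of 35 G1/S genes 19 fell, or 30 adjusted over the list alone, and all 35 were below 0 (median -0.21), among them Rrm2 of ribonucleotide reductase (log2 change -0.48) and the replicative helicase gene Mcm5 (-0.37). Of 27 spindle genes 9 fell, or 15 adjusted over the list alone (median -0.18), including Cep55 (-0.53) and the kinesin Kif11 (-0.51). Camera adjusted p were 1.3e-15, 4.1e-12 and 1.1e-05 for the 3 lists. In the same order they had adjusted p = 0.341, 0.286 and 0.362 with an estimated correlation, and fry gave adjusted p of 0.00191, 0.00189 and 0.00581. Macrophage genes were lower in the same libraries (median -2.43), and with their score as a covariate, added after seeing the data, 19 G2/M, 2 G1/S and 5 spindle genes were called lower and 1 G2/M gene higher, with medians of -0.43, -0.28 and -0.34. Of 680 Reactome pathways camera called 8 higher and 47 lower, mitotic prometaphase among the lower (median -0.13, camera adjusted p = 2.1e-05, adjusted p = 0.972 with an estimated correlation).

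Glycolysis and hypoxia genes rose as a group in the libraries labelled Het. Of 27 glycolysis and hypoxia genes 20 rose and none fell, or 23 and none adjusted over the list alone. The prolyl hydroxylase P4ha2 rose from 128 to 208 CPM, the mitophagy receptor Bnip3 from 40.8 to 83.3 CPM, the oxygen sensor Egln3 by 1.07 and the hexokinase Hk1 by 0.33 on the log2 scale (list median 0.33, camera adjusted p = 1.1e-11, adjusted p = 0.258 with an estimated correlation). With the macrophage score as a covariate, added after seeing the data, 6 of them were called higher, or 18 adjusted over the list alone (median 0.36), beside the lower macrophage genes (-2.43). Among 30 matrix genes 8 rose and 4 fell (9 and 6 adjusted over the list alone). Fibronectin, Fn1, rose from 8349 ± 227 to 12015 ± 698 CPM (SD, n = 3, edgeR adjusted p = 6.8e-05); the list's median was 0.10 and its mean -0.09 (camera adjusted p = 0.128). Tgfbi, a matrix protein induced by TGF-beta, rose by 1.47 on the log2 scale; 3 of 19 TGF-beta targets rose and 3 fell. Of 18 imprinted genes 5 fell (1 higher and 8 lower adjusted over the list alone), among them Dlk1, a Notch-related ligand, from 553 to 207 CPM (median -0.43, camera adjusted p = 0.00343, adjusted p = 0.677 with an estimated correlation). Of 30 interferon-stimulated genes 6 fell, also 6 adjusted over the list alone, with Cxcl10 at -2.03 (median -0.51, camera adjusted p = 0.00272, adjusted p = 0.734 with an estimated correlation). The 33 ribosomal protein genes had none past the test and a median of 0.05 (camera adjusted p = 0.00633, adjusted p = 0.734 with an estimated correlation). With the macrophage score none of the 18 imprinted and 30 interferon genes passed (5 imprinted genes lower and no interferon gene adjusted over the list alone). The imprinted median was then -0.30 (camera adjusted p = 0.00276, adjusted p = 0.711 with an estimated correlation) and the interferon median -0.48 (camera adjusted p = 0.013, adjusted p = 0.882 with an estimated correlation). The ribosomal call ended with the score (camera adjusted p = 0.0718), and 1 matrix gene was higher and none lower. The interferon list was not called without WT 1 (camera adjusted p = 0.115), nor the ribosomal list without WT 2 (0.089) or Het 3 (0.059). Counts of rises and falls were 6 and 3 of 27 p53 targets, 3 and 3 of 26 SRF targets, 1 and 7 of 22 YAP targets, 3 and 4 of 23 senescence genes, 6 and 1 of 25 endoplasmic reticulum stress genes, 0 and 1 of 23 cholesterol genes, 2 and 1 of 36 Hox genes and 2 and 3 of 15 immediate early genes; camera called none of these lists, though with the score it called p53 targets higher (median 0.35, camera adjusted p = 0.00276, adjusted p = 0.553 with an estimated correlation).

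Markers of other cell types differed between Het and WT fibroblast cultures. Of 11 macrophage genes 9 fell, or 11 adjusted over the list alone (median -2.43, camera adjusted p = 1.2e-07, adjusted p = 0.362 with an estimated correlation). Csf1r, the receptor that macrophages need for survival, fell from 24.3 ± 2.89 to 4.48 ± 3.49 CPM (SD, n = 3, edgeR adjusted p = 0.0105), and Cd68 and Fcgr3 fell by 1.31 and 2.28 on the log2 scale. The macrophage score averaged 3.50 in WT and 0.798 in Het, where the libraries lay at 2.15, -0.59 and 0.83. Stab1, Emr1 and Cd36, named above, fell along with it. With that score as a covariate, a setting added after seeing the data, 382 genes passed instead of 2362, 357 of them among the 2362; Ucp2 was at 3.45, Nek2 at -0.73 and Stab1 at -0.51 on the log2 scale. Of 6 mesothelial genes 4 fell (5 adjusted over the list alone), Upk3b from 10.0 ± 1.14 to 1.71 ± 0.29 CPM (median -2.17, camera adjusted p = 1.3e-04, adjusted p = 0.258 with an estimated correlation). Of 7 skeletal muscle genes 2 rose (5 adjusted over the list alone), the embryonic myosin Myh3 by 3.92 and Myh8 by 2.27 on the log2 scale (median 0.83, camera adjusted p = 0.00929, adjusted p = 0.258 with an estimated correlation), and of 8 lung mesenchyme genes 1 rose and 3 fell (median -0.44, camera adjusted p = 0.0485, adjusted p = 0.286 with an estimated correlation). With the macrophage score 1 mesothelial gene was called lower (median -1.38, camera adjusted p = 0.00295) and no skeletal muscle gene passed (median 0.70, camera adjusted p = 0.0293), both with adjusted p = 0.339 with an estimated correlation. No lung mesenchyme gene passed with the score either (median -0.55), and that list's call ended with the score (camera adjusted p = 0.164) and with sex as a covariate (0.0515), also added after seeing the data. The lung mesenchyme list was not called without WT 1 (camera adjusted p = 0.115), WT 2 (0.0729), Het 1 (0.102), Het 2 (0.122) or Het 3 (0.059).

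**Figure D2:**
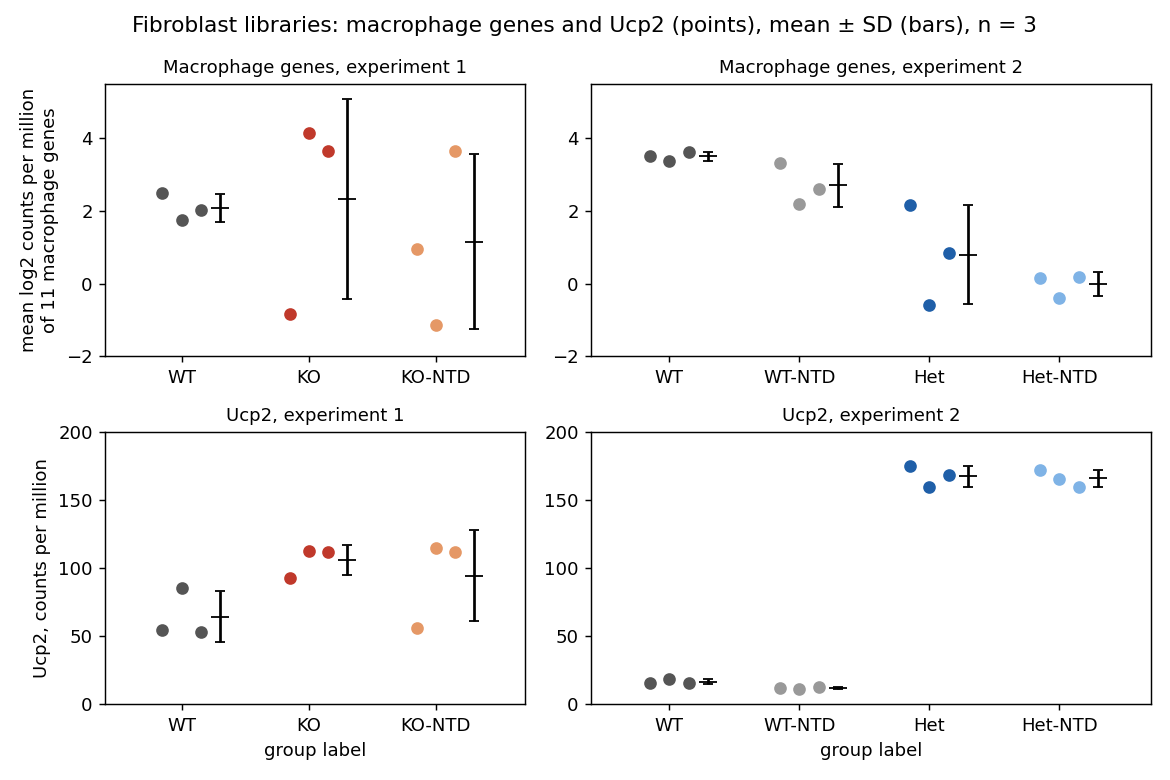
Mean log2 CPM of 11 macrophage genes (upper panels) and Ucp2 in CPM (lower panels) for each fibroblast library (points), with the mean ± SD of 3 libraries, in experiments 1 and 2. The macrophage genes span -0.84 to 4.15 within KO, and Ucp2 is 16.7 CPM in WT and 167 CPM in Het of experiment 2.

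Cell cycle genes were called lower in both KO of experiment 1 and Het of experiment 2, which have no library in common. Genes lower in both numbered 34 against 4.07 for independent lists, and genes higher in both 9 against 1.42. All 14 G2/M genes that fell in KO also fell in Het. Outside mitosis, Mgp fell by 2.01 and 1.80, Arl5a, an Arf-like GTPase, by 0.59 and 1.24, and Fhl1 by 0.63 and 0.75 on the log2 scale in KO and Het, while Mlkl rose by 1.10 and 1.22, Ifi204 by 1.41 and 1.02 and the protease Pappa by 0.46 and 0.89. Serpine2 was the 1 gene called in opposite directions (0.68 in KO, -0.83 in Het). Of the 65 genes called in KO, 60 had the same sign in Het (92.3%). Across the 40 G2/M genes the log2 changes had Pearson r = 0.67 and Spearman rho = 0.74. Across all 14176 genes tested in both, Pearson r was -0.04 and Spearman rho 0.11. Genes are not independent replicates, so no p-value is given. With genes of an average log2 CPM of at least 3, r was 0.17.

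**Figure D3:**
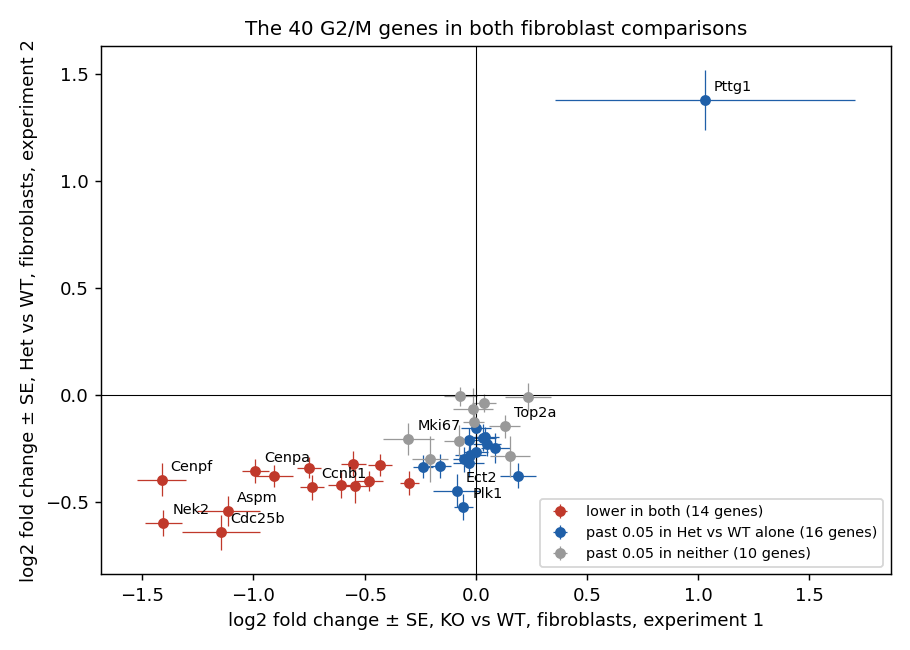
Log2 fold changes ± SE of the 40 G2/M genes in KO against WT of experiment 1 (horizontal) and Het against WT of experiment 2 (vertical), with colours for genes past 0.05 in both, in Het alone or in neither. The 14 genes lower in both lie at the lower left, and Pttg1 (1.38 in Het) lies alone at the upper right.

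KO-NTD against KO set the libraries labelled KO with and without NTD side by side. Foxm1 rose by 1.31 ± 0.06 on the log2 scale (SE, edgeR adjusted p = 1.8e-04), from 146 to 362 CPM, and it was the 1 gene that passed. The next 2 by p-value were the chemokine receptor Ackr3 (8.42 ± 1.15 against 17 ± 1.10 CPM, SD, n = 3; edgeR adjusted p = 0.0715) and the transcription factor Arnt2 (15.2 ± 0.57 against 21.6 ± 0.13 CPM, edgeR adjusted p = 0.12). None of the 40 G2/M genes passed (median 0.03, camera adjusted p = 0.101), though camera called the list higher without KO 2 (0.0325), without KO-NTD 2 (0.0236) and with the macrophage score as a covariate (0.0309), and its median was 0.01 without KO 1 or KO-NTD 3. The mean log2 CPM of the 14 G2/M genes that fell in KO was 5.58, 5.72 and 5.65 in KO, 5.67, 5.62 and 5.68 in KO-NTD and 6.40, 6.52 and 6.47 in WT. The interferon list was lower, with all 30 genes below 0 (median -0.76, camera adjusted p = 3.1e-04, adjusted p = 0.961 with an estimated correlation). It was not called without KO 2 (camera adjusted p = 0.0815), KO 3 (0.0675) or KO-NTD 2 (0.099). All 11 macrophage genes were below 0 as well, with none past the test (median -0.93, camera adjusted p = 0.113), and their score was -0.84, 4.15 and 3.65 in KO 1, 2 and 3 and 0.958, -1.15 and 3.66 in KO-NTD 1, 2 and 3. With that score as a covariate, added after seeing the data, the interferon median was -0.22 (camera adjusted p = 0.0121, adjusted p = 0.748 with an estimated correlation). Camera called 6 lists higher and 3 lower of 31, and none held with an estimated correlation (smallest adjusted p = 0.776 with an estimated correlation). Of 687 Reactome pathways camera called 61 higher and 7 lower, and none held either (smallest adjusted p = 0.821 with an estimated correlation). DESeq2 called 27 genes, and 29 passed in edgeR without KO 1.

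KO-NTD against WT set the libraries labelled KO-NTD beside those labelled WT. Foxm1 rose by 1.41 ± 0.06 on the log2 scale (SE, edgeR adjusted p = 9.9e-05). Mlkl (1.13 ± 0.15 SE) and Ifi204 (1.07 ± 0.14) rose on the log2 scale, as did the interferon-inducible Mnda (0.87) and the Rac regulator Arhgap24 (0.65). The cartilage collagen Col2a1 fell from 867 ± 136 to 44.0 ± 27.2 CPM (SD, n = 3; log2 change -4.30, edgeR adjusted p = 0.0409), Mgp by 2.57, and the developmental factors Zic2 by 2.51, Foxd1 by 2.39 and Msx2 by 2.14. Of 14551 genes 9 rose and 55 fell (edgeR; DESeq2 146 and 255), and 42 of the 65 genes called in KO were called the same way. Of the G2/M genes 13 fell (2 higher and 16 lower adjusted over the list alone; median -0.05, camera adjusted p = 6.8e-06, adjusted p = 0.761 with an estimated correlation). The 13 fell to 8 without WT 2, WT 3, KO-NTD 1 or KO-NTD 2, and the median was -0.12 without KO-NTD 3, -0.09 without WT 1 and -0.08 without WT 3. KO and KO-NTD share the WT libraries: the correlation of their log2 changes across genes was 0.63 against 0.50 in simulated unchanged groups, and the covariance 0.126 against 0.0618. Genes called in both numbered 38 lower and 4 higher, against 0.178 and 0.0111 for independent lists and 0 and 0 in the simulated groups; part of the excess may come from the shared libraries. Without WT 1, KO-NTD 2 or KO-NTD 1 the count of 64 was 34, 39 and 41; Mgp, Zic2 and Msx2 passed without any 1 library, and Col2a1 did not pass without KO-NTD 1 (edgeR adjusted p = 0.161).

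Het-NTD against Het did the same for the libraries labelled Het. Foxm1 rose by 1.42 ± 0.10 on the log2 scale (SE, edgeR adjusted p = 3.4e-04). The receptor gene Notch1 fell from 81.7 ± 2.43 to 66.0 ± 0.53 CPM (SD, n = 3; log2 change -0.31 ± 0.04, edgeR adjusted p = 0.0322), and the carbonic anhydrase relative Car8 did not pass (-1.98, edgeR adjusted p = 0.142). DESeq2 called 23 genes. Camera called 7 lists higher and 5 lower of 32, none held with an estimated correlation (smallest adjusted p = 0.254 with an estimated correlation) and fry called 0 (smallest adjusted p = 0.11). Immediate early genes were lower (median -0.18, camera adjusted p = 3.2e-06, adjusted p = 0.254 with an estimated correlation; 4 lower adjusted over the list alone and none over all genes), and macrophage genes too (median -1.32, camera adjusted p = 0.00123, adjusted p = 0.64 with an estimated correlation), though not called without Het 1 (camera adjusted p = 0.393). G2/M genes were higher by a median of 0.07 (camera adjusted p = 2.8e-04, adjusted p = 0.64 with an estimated correlation), with none past the test. Het-NTD libraries were from 3 males and Het libraries from 2 females and 1 male. The G2/M median was 0.03 with sex and 0.03 with the macrophage score as a covariate, both added after seeing the data, and 0.10 without Het 2. Notch1 passed without Het 1 (0.0436) but not without Het 2 (0.112), Het 3 (0.201), Het-NTD 1 (0.27), Het-NTD 2 (0.238) or Het-NTD 3 (0.176), by edgeR adjusted p.

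Het-NTD against WT set the libraries labelled Het-NTD beside those labelled WT. Foxm1 rose by 1.24 ± 0.10, Brinp3 by 4.05, Ucp2 by 3.31, Rbp4 by 2.77, Hhipl1 by 2.49 and Tnfrsf26 by 2.30 on the log2 scale. Lrrtm3 fell by 7.37, Trim12a by 6.89, Cd36 by 5.37, the complement receptor C5ar1 by 4.76 and Fcrls, a gene of microglia and macrophages, by 4.69 (edgeR adjusted p from 3.8e-11 for Ucp2 to 0.00632 for Fcrls). Of 14314 genes 1200 rose and 1411 fell, and 1751 of the 2362 genes called in Het were called the same way. G2/M genes fell in 21 cases and rose in 1 (23 and 1 adjusted over the list alone; median -0.21, camera adjusted p = 2.9e-10, adjusted p = 0.384 with an estimated correlation). Glycolysis genes rose in 21 of 27 cases (24 adjusted over the list alone; median 0.40, camera adjusted p = 2.7e-13, adjusted p = 0.264 with an estimated correlation), and all 11 macrophage genes fell (median -3.90). The shared WT libraries add covariance: it was 0.42 for Het with Het-NTD against 0.0372 in simulated groups, with a correlation of 0.88 against 0.51. Genes called in both numbered 811 higher and 940 lower, against 94.7 and 121 for independent lists. The macrophage score as a covariate, added after seeing the data, left 91 genes past the test, with 5 G2/M genes lower and 1 higher (median -0.36) and 1 glycolysis gene higher (median 0.49). Without Het-NTD 1 or Het-NTD 2 the count was 1555 and 1622.

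WT-NTD against WT gave Foxm1 (log2 change 1.24 ± 0.10 SE, edgeR adjusted p = 0.00137) and 1 further gene. Phyhip, a gene expressed in brain, rose from 0.197 ± 0.07 to 3.36 ± 0.20 CPM (SD, n = 3; log2 change 4.07, edgeR adjusted p = 0.0032), and Ucp2 at 11.8 against 16.7 CPM did not pass (edgeR adjusted p = 0.0548). All 23 cholesterol synthesis genes were above 0 (median 0.11, camera adjusted p = 1.9e-07, adjusted p = 0.891 with an estimated correlation; 2 higher adjusted over the list alone and none over all genes). Camera called 3 lists higher and 3 lower of 32, none held with an estimated correlation (smallest adjusted p = 0.891 with an estimated correlation) and fry called 0 (smallest adjusted p = 0.544). Endoplasmic reticulum stress genes (median 0.11, camera adjusted p = 0.0116) and ribosomal protein genes (0.03, 0.0379) were higher with none past the test. G1/S genes (median -0.08, camera adjusted p = 8.4e-06), G2/M genes (-0.04, 0.00911; 32 of 40 below 0) and macrophage genes (-0.71, 0.00165; 11 of 11 below 0) were lower, also with none past the test. The G2/M list turned direction without WT-NTD 1 (camera adjusted p = 0.98, median 0.01) and was not called without WT 3 (0.153), and its median was -0.07 without WT 1, -0.10 without WT-NTD 3 and -0.08 with the macrophage score, added after seeing the data. The stress list was not called without WT 3 (camera adjusted p = 0.22), WT-NTD 2 (0.156) or WT-NTD 3 (0.0622), the ribosomal list without WT 1 (0.0577), WT 2 (0.594), WT-NTD 1 (0.658) or WT-NTD 2 (0.0534), and the macrophage list without WT-NTD 2 (0.15). With the macrophage score the stress and ribosomal calls ended (camera adjusted p = 0.065 for both), and spindle genes were called lower (0.0335) and p53 targets higher (0.0153). DESeq2 called 28 genes, and without WT 1 or WT-NTD 3 edgeR called 119 and 4. The difference of the NTD effect between Het and WT gave 0 of 14314 genes (edgeR; 711 at an unadjusted p under 0.05, DESeq2 4). The lowest p was that of the death receptor gene Tnfrsf10b (log2 difference -0.53, edgeR adjusted p = 0.259), followed by Phyhip (-3.42) and Ucp2 (0.48, edgeR adjusted p = 0.892 for both), and Foxm1 differed by 0.18 (edgeR adjusted p = 0.903). Leaving out Het 1 gave 2 genes, and leaving out WT 1, WT-NTD 1 or WT-NTD 3 gave 1.

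In whole lung no gene passed between Het and WT. Of 15933 genes edgeR called 0, with 114 at an unadjusted p under 0.05, and DESeq2 called 1, D430041D05Rik (log2 change -1.57, 3.19 ± 0.75 against 9.50 ± 1.17 CPM, SD, n = 3, edgeR adjusted p = 1). The next by p-value were Pcdhb6, of a clustered protocadherin family (-1.69), and Pigr, the epithelial immunoglobulin transporter (8.44 ± 3.15 against 20.9 ± 4.89 CPM), both with edgeR adjusted p = 1. As a group, 37 of 40 G2/M genes were below 0 (median -0.19, none past the test; camera adjusted p = 7.1e-12, adjusted p = 0.667 with an estimated correlation). Without Het 3 that list was not called (camera adjusted p = 0.165), and its median was -0.09 without Het 3, -0.33 without Het 2 and, in a setting added after seeing the data, -0.11 without WT 1 and Het 3 together. Spindle genes (median -0.08), senescence genes (-0.19) and immediate early genes (-0.15) were lower with camera adjusted p of 0.00111, 0.00411 and 0.00673, each with adjusted p = 0.418 with an estimated correlation. G1/S genes (median -0.05, camera adjusted p = 0.00991, adjusted p = 0.744 with an estimated correlation) and cholesterol genes (-0.09, 0.0036, adjusted p = 0.441 with an estimated correlation) were also lower. Of 9 neutrophil genes 8 were above 0 (median 0.54, camera adjusted p = 1.5e-07, adjusted p = 0.418 with an estimated correlation), and 7 adipocyte genes (median 0.70, 0.0148) and 9 T cell genes (0.19, 0.0428) were higher, both with adjusted p = 0.744 with an estimated correlation. WT 1 and Het 3 stood apart on the first principal component, which held 49.0% of the variance (Het 3 at 44.2, WT 1 above it, and the other 4 libraries from -38.7 to -11.1). Without Het 3 the G1/S and adipocyte lists turned direction (camera adjusted p = 0.949 and 0.723), and the spindle (0.53), senescence (0.0741), immediate early (0.574), neutrophil (0.107) and T cell lists (0.723) were not called. Calls also ended for adipocyte (0.175), cholesterol (0.0649) and T cell genes (0.798) without WT 1, for G1/S (0.17) and T cell genes (0.0985) without WT 2, and for cholesterol (0.0701), senescence (0.0657) and T cell genes (0.0948) without Het 2. Without both WT 1 and Het 3 the T cell list turned direction (0.696).

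Markers of the lung's own cell types gave no call with all 6 libraries. Camera adjusted p and median log2 changes were 0.288 and 0.12 for alveolar type 2 genes, 0.155 and 0.11 for alveolar type 1, 0.331 and 0.12 for ciliated, 0.86 and 0.12 for club, 0.307 and 0.09 for endothelial, 0.749 and 0.15 for lymphatic and 0.928 and 0.04 for macrophage genes. Likewise they were 0.051 and 0.15 for B cell, 0.178 and -0.01 for thymocyte, 0.287 and -0.09 for lung mesenchyme, 0.803 and 0.05 for mesothelial, 0.0802 and -0.08 for smooth muscle, 0.263 and -0.19 for cardiac, 0.165 and -0.28 for skeletal muscle, 0.803 and -0.08 for keratin, 0.621 and -0.02 for neural and 0.297 and -0.07 for chondrocyte genes. For skeletal muscle and keratin genes the test's direction was higher although the median was below 0, and for club and thymocyte genes the mean (-0.07 and 0.28) had the other sign. Interferon genes (0.335), p53 (0.697), SRF (0.0587), YAP (0.142) and TGF-beta targets (0.484), matrix (0.0802), endoplasmic reticulum stress (0.314), glycolysis (0.0713), Hox (0.682), imprinted (0.354) and ribosomal protein genes (0.287) gave no call either by camera adjusted p, nor did Xist with the Y-linked genes (0.297), whose libraries were from 2 females and 1 male in WT and 1 female and 2 males in Het. Some of these lists were called when 1 library was left out: endothelial (0.0472), interferon (0.00356) and cardiac genes (0.00205) without WT 1, ciliated (0.0145), B cell (0.00694), matrix (0.00601) and skeletal muscle genes (0.00223) without WT 2, thymocyte (2.0e-04), B cell (0.00115) and SRF genes (0.017) without WT 3, alveolar type 1 (0.0416), club (0.0402) and smooth muscle genes (4.7e-04) without Het 1, B cell genes (0.00725) without Het 2 and ribosomal protein (1.2e-06), matrix (0.0141) and ciliated genes (0.0471) without Het 3, among others. Erythroid and liver genes had 3 and 4 tested members, too few for a test, with medians of 0.29 and 0.34, and none of the 13 mitochondrially encoded genes was in the table. Of 702 Reactome pathways camera called 6 lower, with mitotic prometaphase at a median of -0.07 (camera adjusted p = 5.3e-04), with adjusted p = 0.9996 with an estimated correlation.

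The Het effect in lung minus that in fibroblasts was tested gene by gene in the joint fit. Of 16364 genes 133 had a higher difference and 51 a lower one (edgeR; DESeq2 512 and 222). Ucp2 was 188 ± 9.49 CPM in Het and 18.8 ± 1.73 CPM in WT fibroblasts but 360 ± 27.7 and 325 ± 15.9 CPM in Het and WT lung (SD, n = 3; log2 difference -3.18 ± 0.13 SE, edgeR adjusted p = 8.7e-07). Trim12a was 0.0731 and 5.64 CPM in Het and WT fibroblasts and 18.0 and 17.2 CPM in lung (log2 difference 6.23 ± 0.47, edgeR adjusted p = 1.7e-04). Its neighbour in the gene family Trim30d had 0 counts in the 3 Het fibroblast libraries and 246 in WT, and 8.21 against 7.99 CPM in lung (edgeR adjusted p = 2.0e-04). Against a floor of 3 counts over the group Trim30d was 86.4-fold lower in Het fibroblasts, and the 95% counting interval of the ratio began at 69.8. Lrrtm3 (log2 difference 6.13), the endothelial receptor Eltd1 (-4.54), Rbm46 (-3.68) and the cartilage protein Cilp (-3.30) also passed. A further 2 genes rested on few fibroblast counts, Ces2e on 32 in WT and 1 in Het, and Esrp1 on 0 and 12. Mesothelial genes differed (median 2.11, camera adjusted p = 4.0e-08, adjusted p = 0.126 with an estimated correlation), as did macrophage genes (2.43, 3.5e-10, adjusted p = 0.4 with an estimated correlation) and glycolysis genes (-0.40, 1.9e-11, adjusted p = 0.156 with an estimated correlation); the 40 G2/M genes gave no call (0.12, 0.407), and their median was -0.05 without lung Het 2, 0.04 without lung WT 1 and 0.18 without lung Het 3, where the list was called (0.00374). Across 13836 genes the Het effects in the 2 tissues had Pearson r = 0.04, and 1221 of 2297 genes called in fibroblasts had the same sign in lung (53.2%). The count of 184 was 39 without lung WT 3, 50 without lung WT 2, 58 without lung Het 2, 62 without lung WT 1, 63 without fibroblast Het 3, 99 without fibroblast WT 2, 100 without fibroblast Het 2, 121 without lung Het 1 and 546 without lung Het 3; Trim30d, Trim12a, Lrrtm3, Eltd1, Rbm46 and Ucp2 passed without any 1 library.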

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

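The tests in this part were chosen before their results were seen. The Het effect differed between tissues for 184 genes by the test of the difference itself (edgeR, lung minus fibroblasts, 3 libraries per group). Of 60 splits drawn of the 12 libraries within tissue, 5 gave as many genes, the real one included, and the highest of the others gave 804, so chance is not excluded and the libraries hold a structure that some other splits follow. By log2 difference, Trim12a was at 6.23, Lrrtm3 at 6.13 and Ces2e at 4.84, all lower in Het than in WT fibroblasts. Trim30d had a fitted value of 9.62, which is no bound because Het fibroblasts had 0 counts. Against a floor of 3 counts over the group it was 86.4-fold lower there, and the 95% counting interval of the ratio began at 69.8. Esrp1 was at -5.25, Eltd1 at -4.54, Rbm46 at -3.68, Cilp at -3.30 and Ucp2 at -3.18, all higher in Het than in WT fibroblasts. Ces2e and Esrp1 rested on at most 32 fibroblast counts in a group. Esrp1 had 0 counts in WT fibroblasts, so its fitted value is no bound either.

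As groups, macrophage genes differed between the tissues by a median of 2.43 (camera adjusted p = 3.5e-10, adjusted p = 0.4 with an estimated correlation) and mesothelial genes by 2.11 (4.0e-08, adjusted p = 0.126 with an estimated correlation). Interferon-stimulated genes differed by 0.64 (0.00128) and G1/S genes by 0.15 (0.025), both with adjusted p = 0.881 with an estimated correlation. The interferon median was 0.33 (camera adjusted p = 0.122) without fibroblast WT 1. The G1/S list was not called without fibroblast WT 3 (0.171), Het 1 (0.143) or Het 2 (0.061), or without lung WT 3 (0.0973), Het 2 (0.0952) or Het 1 (0.235, median 0.08). Glycolysis and hypoxia genes differed by -0.40 (1.9e-11, adjusted p = 0.156 with an estimated correlation), and fry gave them adjusted p = 0.0173.

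Between genotypes, the NTD effect in Het minus that in WT differed for 6 lists although 0 genes passed by edgeR (711 at an unadjusted p under 0.05, DESeq2 4). Cell cycle lists had higher differences, with medians of 0.14 for G2/M genes (36 of 40 above 0), 0.13 for G1/S genes and 0.12 for spindle genes. Lower differences were seen for cholesterol synthesis genes (-0.16, 23 of 23 below 0), p53 targets (-0.18) and matrix genes (-0.12). Camera adjusted p in that order were 1.9e-07, 3.6e-08, 7.6e-05, 1.6e-08, 0.00686 and 0.0146, and each list had adjusted p = 0.679 with an estimated correlation. Without WT-NTD 1 the medians were 0.08 for G2/M and 0.07 for spindle genes, and -0.06 for p53 targets, which were then not called (0.244), nor without WT 1 (0.0786) or Het 1 (0.068), and were at -0.11 without Het-NTD 2. Matrix genes were at -0.21 without WT 1 and not called without WT 3 (0.385, median -0.04), WT-NTD 2 (0.148) or Het 3 (0.116). Splits bear on neither the lists nor the count: all 60 give at least the 0 genes of the real one by construction (highest other 40). The libraries of both differences were compared without an explanation being tested.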

How the results depend on the processing

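The covariates (sex, macrophage score) and the lung without WT 1 and Het 3 together were chosen after seeing the data; the cause was not tested for any change below unless given. DESeq2 called 479 genes for KO against WT, 27 for KO-NTD against KO, 23 for Het-NTD against Het, 1 in lung, 401 for KO-NTD against WT, 28 for WT-NTD against WT, 4 for the NTD difference and 734 for the tissue difference. No filter on low counts gave 2 genes for KO-NTD against KO and 5 for WT-NTD against WT. Fits of the compared groups alone, which hold fewer libraries, gave 36 for KO, 1389 for Het (1350 of them among the 2362), 20 for Het-NTD against Het, 100 for KO-NTD against WT and 1 for WT-NTD against WT. Sex as a covariate gave 36 for KO (35 among the 65), 1 for Het-NTD against Het and 121 for the tissue difference. The macrophage score gave 430 for KO (all 65 among them), 2 for KO-NTD against KO, 382 for Het, 1 for Het-NTD against Het, 267 for KO-NTD against WT and 91 for Het-NTD against WT, and turned Fcrls and Nnat in Het-NTD against WT to 0.026 and 0.15. With that score the Foxm1 log2 change in Het against WT was -0.01, and without it -0.18. The score's slope there also rests on the NTD libraries, so this change does not separate macrophages from genotype. RLE size factors gave 67 genes for KO and 2344 for Het.

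The replicate numbers do not pair the libraries throughout, but pairing of NTD libraries with the matching group without NTD is not excluded. By number, sexes matched between KO and KO-NTD and between WT and WT-NTD of experiment 2. Het 2 and Het 3 were female, while Het-NTD 2 and Het-NTD 3 were male. For numbers 1, 2 and 3, deviations had r = 0.17, -0.48 and 0.61 for KO with KO-NTD and 0.24, 0.45 and 0.07 for WT with WT-NTD. Deviations of same-numbered libraries correlated above 0.1 in 5 of 9 pairs in experiment 1 (r from -0.48 to 0.61), 6 of 18 in experiment 2 (-0.21 to 0.45) and 1 of 3 in lung (-0.34 to 0.12), and the best match had the same number in 4, 8 and 0 of them. With the replicate block 52 genes were called for KO, 2557 for Het, 1 for Het-NTD against Het, 4 for WT-NTD against WT and 79 for the tissue difference.

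Leaving out 1 library gave 24 to 142 genes for KO, 1 to 29 for KO-NTD against KO, 1304 to 2547 for Het, 1 to 3 for Het-NTD against Het, 0 to 0 in lung, 34 to 55 for KO-NTD against WT, 2 to 119 for WT-NTD against WT, 1555 to 2769 for Het-NTD against WT, 0 to 2 for the NTD difference and 39 to 546 for the tissue difference. Libraries that moved one of these counts of genes by over 1.5 times are named beside it in the results; for Het-NTD against Het the count was 1 without Het-NTD 1, Het-NTD 3 or Het 3. Foxm1 stayed on its side of the threshold in all of these fits, with log2 changes of 0.07 to 0.14 in KO, -0.20 to -0.17 in Het, -0.12 to -0.00 in lung, 1.253 to 1.37 in KO-NTD against KO, 1.36 to 1.498 in Het-NTD against Het and 1.10 to 1.35 in WT-NTD against WT. Over named genes these fits gave 9571 outcomes on the same side, 399 no longer past the threshold and 74 newly past it.

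Lists that turned direction had these camera adjusted p without 1 library. Glycolysis in KO spanned 1.9e-04 to 0.432 (turned without KO 1). In lung G1/S spanned 2.7e-04 to 0.949 and adipocyte 6.1e-06 to 0.723 (Het 3), cardiac 0.00205 to 0.723 (WT 2), skeletal muscle 7.1e-13 to 0.688 and keratin 0.00831 to 0.921 (WT 1). In WT-NTD against WT, G2/M spanned 6.0e-08 to 0.98 (WT-NTD 1), glycolysis 0.0344 to 0.786 (WT 2) and interferon 0.00663 to 0.989 (WT 3). Macrophage genes spanned 0.00983 to 0.995 in the NTD difference (Het 2), and ribosomal genes 0.00402 to 0.969 in the tissue difference (lung Het 3). Without lung WT 1 and Het 3 together, T cell (0.696), skeletal muscle (5.0e-04) and adipocyte genes (0.471) turned. With an estimated correlation all 86 list calls were lost, and the 245 unchanged outcomes were lists called in neither setting. Fry lost 63 of the 86 calls and added 2. Reactome pathways called by camera numbered 29 higher and 21 lower for Het-NTD against Het and 29 and 6 for the NTD difference. They numbered 3 and 1 for WT-NTD against WT and 4 and 5 for Het-NTD against WT. No pathway held in any comparison with an estimated correlation.

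Across genes of an average log2 CPM of at least 3, r was 0.17 between KO and Het (-0.04 over all genes), 0.0881 between KO and lung Het, and 0.0397 between KO-NTD against KO and Het-NTD against Het (0.20 over all). In the lung 40% of genes changed 2-fold were recovered in simulated data, so smaller differences were mostly out of reach there at this depth and number of libraries.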

Other observations

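The single-library, transcript, cycling-cell and Het-overlap tests were chosen after their results were seen; the positional, slope, sex and macrophage-score tests were added after the data were seen. With the macrophage score as a covariate, 430 genes passed in KO against WT (edgeR), all 65 of those called without it among them. Of 30 interferon-stimulated genes 6 rose, or 20 adjusted over the list alone (median 0.87, camera adjusted p = 7.7e-14, adjusted p = 0.677 with an estimated correlation). Ifi44 rose by 1.959 on the log2 scale (edgeR adjusted p = 0.0178), Ifi203 by 1.67 and Ifit1, which binds viral RNA, by 1.58 (edgeR adjusted p = 0.0376). Of 22 YAP targets 4 fell and 0 rose with the score, and of 27 p53 targets 3 rose and 1 fell. Imprinted genes were called lower (median -0.30, camera adjusted p = 0.0115, adjusted p = 0.772 with an estimated correlation). The purine oxidase Xdh rose by 2.63, the iron carrier transferrin, Trf, by 2.42, the complement gene C4b by 2.05 and the matrix protein dermatopontin, Dpt, by 1.78. Brinp3 rose by 2.85 (edgeR adjusted p = 0.00476) and Naalad2 by 1.74, and both were also higher in Het fibroblasts. Lower were the endothelial phosphatase Ptprb (-1.83), Ctla2a (-1.67), the Notch target Heyl (-1.56) and the transcription factor Gata3 (-1.42). These genes were chosen after their values were seen.

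Some genes outside the lists were called the same way in both fibroblast experiments, and those named here were chosen for it after their values were seen. Arl5a was 106 ± 4.12 CPM in KO against 159 ± 7.46 CPM in WT of experiment 1, and 66.9 ± 0.78 CPM in Het against 158 ± 1.95 CPM in WT of experiment 2 (SD, n = 3). The mitotic gene Troap fell by 0.99 and 0.40 on the log2 scale in KO and Het, Arl6ip1, a shaper of the endoplasmic reticulum, by 0.82 and 0.44, and the cohesin subunit Rad21 by 0.46 and 0.32, while Lhfpl2 rose by 0.54 and 0.50 and Serpinf1, an inhibitor of vessel growth, by 0.39 and 0.48. Of the Trim genes beside Trim12a and Trim30d, Trim34b had 82 counts in Het against 2 in WT fibroblasts (WT to Het ratio 0.0257, 95% counting interval 0.00306 to 0.0959). KO-NTD against KO correlated with WT-NTD against WT across genes with r = 0.40 and rho = 0.32, in different libraries, and with Het-NTD against Het with r = 0.20 and rho = 0.0079. Macrophage genes had medians below 0 in each of these NTD comparisons, and whether they account for any of the correlation was not tested.

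The 2362 genes called between Het and WT fibroblasts went along with fewer macrophage transcripts. Strain segments that change the genes within them were argued against as the cause of the whole. Of placed calls, 99.2% lay outside the 1 window of 10 Mb with more calls than shuffling gave (chromosome 17, 0 to 10 Mb, 19 of 36 genes against 6.00). That test sees only crowding of calls, so effects of a segment on genes elsewhere were not tested. A second look at the 255 calls of at least 4-fold found 11 in windows on chromosome 6 (60 to 70 Mb, 3 of 14 genes) and chromosome 7 (100 to 110 Mb, 8 of 80, with Ucp2, Trim12a, Trim30d and Trim34b among them). Segments that change their own genes therefore stay open for these 11, and effects of a segment on genes elsewhere stay open for all calls. Ucp2 was at 0.14 in lung Het (edgeR adjusted p = 1). In experiment 1 Trim12a also varied within groups, from 0 to 1.76 CPM in WT and from 0.0356 to 2.14 CPM in KO-NTD. Ucp2 was 64.3 CPM in WT there and 16.7 CPM in WT of experiment 2. With the macrophage score as a covariate 15.1% of the calls passed, below the 25% set beforehand for macrophages as the cause, but the median fold was 1.13 times and the standard error 1.83 times that without the score, groups held 83.6% of the score's variance, and the condition on folds that leaves this test undecided was added after the 15.1% was seen. Slopes on the score within the groups of experiment 1, other libraries, went against the Het folds with r = -0.76 (82.4% of genes), so macrophages in the WT cultures may account for a part, while 40.4% of the sum of squares was left, 1447 called genes had no slope past 0.05 (median absolute log2 change 0.35), and Ucp2 went from 3.33 ± 0.07 to 3.45 ± 0.11 (SE) with the score as Stab1 went from -3.09 ± 0.62 to -0.51 ± 0.17. Lower Foxm1 activity stays open too: over the called genes Pearson r with KO against WT was -0.0135, under the 0.1 set beforehand as arguing against it. Spearman rho was 0.148 with 63.9% of genes of the same sign. The Foxm1 count was not lower in those KO libraries, so KO may be a poor measure of lower Foxm1 activity. The 0.1 was asked of both coefficients only after these values were seen.

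Foxm1 was not lower in the libraries labelled KO. Of the KO libraries, 3 of 3 had a level at or above the lowest WT library. That would argue against a single wild-type library labelled KO only if knockout lowers the Foxm1 count. Since that is not known here, the level cannot decide it. Other values, looked at afterwards, argue against a single wild-type library among the KO libraries. The 40 G2/M genes averaged 6.15, 6.23 and 6.16 log2 CPM in the KO libraries and 6.38, 6.51 and 6.47 in the WT libraries. On principal component 2, with 16.0% of the variance, KO lay at -16.3, -17.4 and -17.5 and WT at 30.3, 29.2 and 22.8. A transcript that is still made and counted could give the fold of 1.07, but gene counts do not separate exons, so it cannot be told apart from other causes here. Mislabelling of the whole group stays open, as does the biology of the allele, which the labels do not describe.

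G2/M genes fell in the libraries labelled KO without the G1/S genes. The test of fewer cycling cells had a fixed outcome, since the pattern was named for G1/S genes that did not fall. It therefore adds no evidence of its own. The G1/S median was -0.0288 (SD of members 0.08), against a G2/M mean of -0.27 and a G2/M median of -0.07. The 26 G2/M genes not called had a median of -0.01. They were picked for missing the same test in the same libraries, so that median cannot show whether a small fall was shared by the whole list. Unequal numbers of females and males was argued against, since 10 of 14 called G2/M genes passed with sex as a covariate and their median was -0.74 with and without it. Lower Foxm1 activity stays open. Of the 14 genes, 14 were called lower in Het of experiment 2 too, but so were 15 of the other 26 members. Foxm1 itself was called lower in neither comparison, though every Het value lay below every WT value in experiment 2. That condition on Foxm1 was added after the overlap was seen, so the overlap decides nothing. A shift in the phases of cycling cells with another origin was not tested and stays open.

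With 3 libraries against 3, the 10 splits are too few for a share under 0.05. As many genes as in the real split, that one included, came from 1 split for KO against WT (65 genes, highest other 1), 1 for Het against WT (2362, highest other 0), 1 for KO-NTD against WT (64, highest other 0), 1 for Het-NTD against WT (2611, highest other 0), 1 for Het-NTD against Het (2, highest other 1), 2 for WT-NTD against WT (2, highest other 2) and 10 in lung (0, highest other 5), where every split gives at least 0 by construction. For KO-NTD against KO it was 2 splits (1 gene, highest other 2457). That other split set KO 1, KO-NTD 1 and KO-NTD 2 against KO 2, KO 3 and KO-NTD 3, which points to a structure of the samples; their macrophage scores were -0.84, 0.958 and -1.15 against 4.15, 3.65 and 3.66.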
